A study of Mus musculus with 8 samples.

How the data were processed

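RNA was measured in hearts of wild-type mice, in 4 sedentary and 4 swimming-trained samples, in a study of aging hearts. Per the labels' protocols, total RNA was depleted of ribosomal RNA by an RNase H method and reverse transcribed with random hexamers, so that transcripts without a poly(A) tail could also be sequenced. Whether the library kit marked the strand is not given in the sources used here, and overlapping or antisense genes can therefore share reads. The labels number biological replicates 1 to 4 in each group but do not say that each came from a separate mouse. The p-values of single genes, single transcripts and per-library measures rest on the spread between these samples. Those of the list test camera, described below, compare genes of a list with other genes. The binomial p given for fat transcripts counts genes.

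The deposited table gives FPKM (fragments mapped to a transcript, scaled by its length and by the size of the library) for each transcript and each of the 8 samples, per the file headers. Per the submitters' processing notes, STAR 2.5.1a, Subread, featureCounts 1.4.6-p5, Salmon 0.8.2 and HISAT2 were used with the build mm10. Which of them produced the FPKM values, with which annotation and filters, is not given in the sources used here. The table holds 51169 transcripts, of which 45742 carry Ensembl identifiers and 5427 carry identifiers of assembled transcripts that the table does not pair with genes. The GENCODE M21 annotation, which is on the same build, named 45676 of the Ensembl transcripts and left 66 unmatched. FPKM values of the named transcripts were summed to 18137 genes. The planned tests had assumed values per gene, and the summing was added because the table turned out to be per transcript. Reads that the authors assigned to assembled transcripts are absent from the gene sums. Assembled transcripts held between 11.3% and 12.5% of the FPKM total of a library. All columns of the table were used.

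Total reads per library are not in the table. The lowest values were searched for the steps that whole reads leave. Genes with 1 transcript and under 0.1 FPKM in both libraries of a pair were compared in all 28 pairs. Between 11.4% and 17.7% of their ratios lay at ratios of small whole numbers within a log2 window of 0.02, against 2.24% to 2.82% at other offsets. That was enough to estimate relative depth, and too few to turn the values back into reads, so no count test was run. Absolute depth is unknown and no counting interval is given.

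Genes with a mean FPKM of at least 0.5 over the 8 libraries were tested on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend, two-sided), with all 8 libraries and no other term. Benjamini-Hochberg adjustment covered all genes tested and a call required an adjusted p below 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of genes with low values. Gene lists were fixed before the data were examined. The 27 pathway lists and 12 cell type lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted within each kind. Another 4 cell type lists had too few tested members. Camera with a correlation estimated per list and fry were run beside it. Single measures were compared by exact two-sided permutation over the 70 assignments of 4 of 8 libraries, where the smallest possible p is 0.0286. Summaries were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

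Genes are named by a rule set before the data were examined. In each direction it takes up to 10 genes with an adjusted p below 0.05, by fold change, with a mean of at least 1 FPKM in the higher group and no provisional name (Gm, Rik or a clone number), and fills the direction to 10 by the smallest unadjusted p. It adds up to 4 members with the smallest p for each list described, every list gene past the threshold over all genes, and 16 genes named whatever their values. Of those 16, Cdkn2a was below the filter. Genes named outside the rule are said to be chosen after their values were seen.

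The fit was tested on simulated data with the means and residual spreads of the 11674 genes tested, in 10 runs with 200 changed genes each. It recovered 39.6% of genes changed by 0.5 log2 units, 74.4% of those changed by 1, 92.0% of those changed by 2 and 97.4% of those changed by 3, with 6.2 false calls per run on average. A shift of -0.1 in the respiratory chain list was called in all 10 runs, and in 1 of 10 runs without any change some list was called. These simulated genes vary independently and with normal noise, which real genes do not. The 200 changed genes of a run also loosen the Benjamini-Hochberg threshold. The shares recovered are therefore not the power of the real comparison, where 2 genes passed. Alternatives covered the pseudocount, the filter, the scaling of the libraries, the replicate number as a block, library weights, the variance model, a permutation test per gene and the removal of each library.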

Results

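The series compares cardiac RNA of sedentary and swimming-trained mice in a study of the aging heart, with 4 libraries per group. The FPKM total ranged from 210413 in swimming replicate 2 to 235461 in sedentary replicate 3. The depth inferred from the lowest values lay between 0.870 and 1.00 times the geometric mean of the libraries in 7 of them and was 1.63 times that mean in swimming replicate 2. Swimming replicate 2 also listed the most transcripts above 0, 43018, against 39942 to 41045 in the other libraries. Correlations of log2 values ranged from 0.942 to 0.951 within groups and from 0.941 to 0.950 between them, so that no pair of libraries looked like a duplicate. The first principal component held 17.5% of the variance and did not separate the groups. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were above 0 in all 8 libraries, with Eif2s3y between 12.0 and 19.1 FPKM.

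Sedentary replicate 4 stood apart by transcripts of other tissues. Alb, the serum albumin made by the liver, was listed there at 23.2 FPKM and at 0.0865 FPKM or less in the other 7 libraries. The major urinary protein gene Mup20 was at 11.6 FPKM there and at 0 elsewhere. Adipocyte genes were also high in this library, with Cfd (adipsin) at 12.0 FPKM against at most 0.668 and Adipoq (adiponectin) at 2.80 FPKM against at most 0.139. These genes were chosen after their values were seen.

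**Figure D1:**
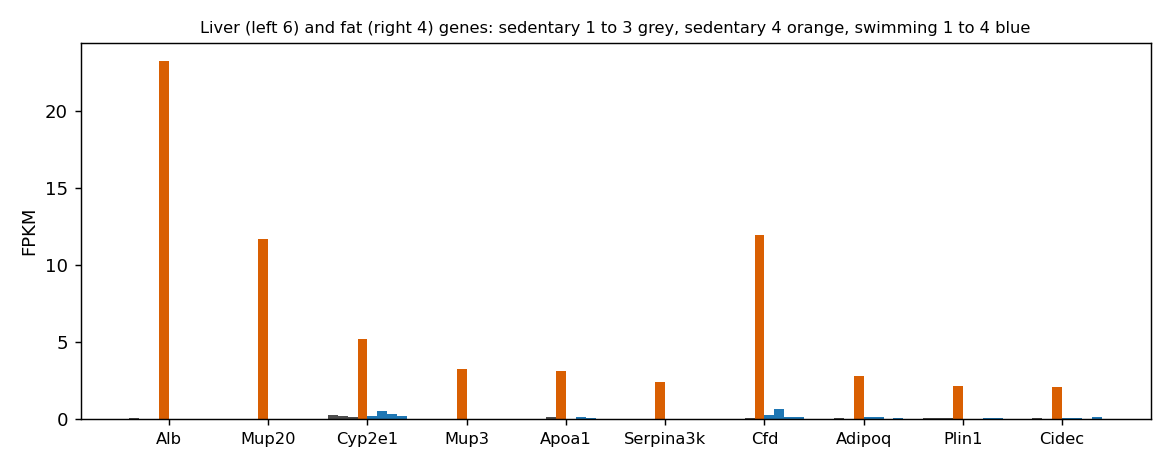
Bars give the FPKM (vertical axis) of 6 liver genes and 4 fat genes in each library, with sedentary replicate 4 in orange, the other sedentary libraries in grey and the swimming libraries in blue. Alb reached 23.2 FPKM and Cfd 12.0 FPKM in sedentary replicate 4, above all other libraries.

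In the comparison of swimming with sedentary hearts, 2 of 11674 genes tested were higher and 0 were lower. Rbpms, which encodes an RNA-binding protein of muscle cells (ENSMUSG00000031586, chromosome 8, 33782643 to 33929863, minus strand, build mm10), rose from 6.46 ± 0.367 to 15.3 ± 1.98 FPKM (SD, n = 4 per group), a log2 fold change of 1.17 (SE 0.0957, limma adjusted p = 0.0234). Ccdc137, a coiled-coil protein gene (ENSMUSG00000049957, chromosome 11, 120458115 to 120464358, plus strand), rose from 0.367 ± 0.141 to 1.69 ± 0.0325 FPKM (log2 fold change 1.35, SE 0.119, limma adjusted p = 0.0234). For both genes all 4 swimming libraries lay above all 4 sedentary libraries. The gene nearest to a call on the lower side was Cyld, which encodes a deubiquitinase that restrains NF-kB signalling (chromosome 8, 88697028 to 88751945, plus strand), at 5.18 ± 0.858 FPKM in sedentary and 1.01 ± 0.378 FPKM in swimming hearts (log2 fold change -1.94, limma adjusted p = 0.0573).

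At an unadjusted p below 0.05 limma found 860 genes, 576 higher and 284 lower, where 583.7 would be expected by chance. With median-of-ratios scaling the split was 398 higher and 452 lower, and with quantile normalization 423 higher and 391 lower, so the excess of higher genes depended on the scaling. In 378 genes all swimming libraries lay above all sedentary ones and in 185 all lay below, together 4.82% of genes against 2.86% by chance. With each library left out in turn, log2 fold changes stayed between 1.10 and 1.25 for Rbpms and between 1.28 and 1.45 for Ccdc137, while calls were lost. The adjusted p of Rbpms ran from 0.00481 to 0.0994 and was 0.0602 without sedentary replicate 1, 0.0691 without sedentary replicate 4, 0.0671 without swimming replicate 1 and 0.0994 without swimming replicate 2. That of Ccdc137 was 0.0112 without sedentary replicate 1 and above 0.05 without sedentary replicate 2 (0.0547), 3 (0.0618) or 4 (0.0691) or swimming replicate 1 (0.0671), 2 (0.124), 3 (0.0543) or 4 (0.0509).

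Other genes with the smallest unadjusted p did not pass the adjustment (limma adjusted p = 0.434 for each). On the higher side these included the macrophage complement receptor gene Vsig4 (0.947 ± 0.135 against 1.65 ± 0.0860 FPKM, sedentary against swimming) and the ficolin gene Fcna (1.12 ± 0.173 against 1.87 ± 0.0911). The matrix protein gene Fbln1 had 17.9 ± 1.23 against 23.1 ± 0.790 FPKM. The histone gene Hist1h3b, Zfp329, Serf2, Smg6 and Zmym3 had log2 fold changes between 0.48 (Serf2) and 1.67 (Zfp329). Reads of histone genes can be shared with near-identical copies. On the lower side were the autophagy protease gene Atg4d (4.47 ± 0.994 against 1.09 ± 0.618 FPKM), Wwc2 (8.64 ± 1.33 against 4.40 ± 0.860) and Prkab2, which encodes a regulatory subunit of AMP-activated kinase (12.97 ± 0.848 against 8.30 ± 1.52). Smyd1, a muscle histone methyltransferase gene, had 118.8 ± 5.37 against 101.4 ± 2.04 FPKM. Rbm5 and Clk1, both regulators of splicing, Chmp6 and the tRNA synthetase gene Qars had log2 fold changes between -0.75 (Rbm5) and -0.35 (Clk1).

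**Figure D2:**
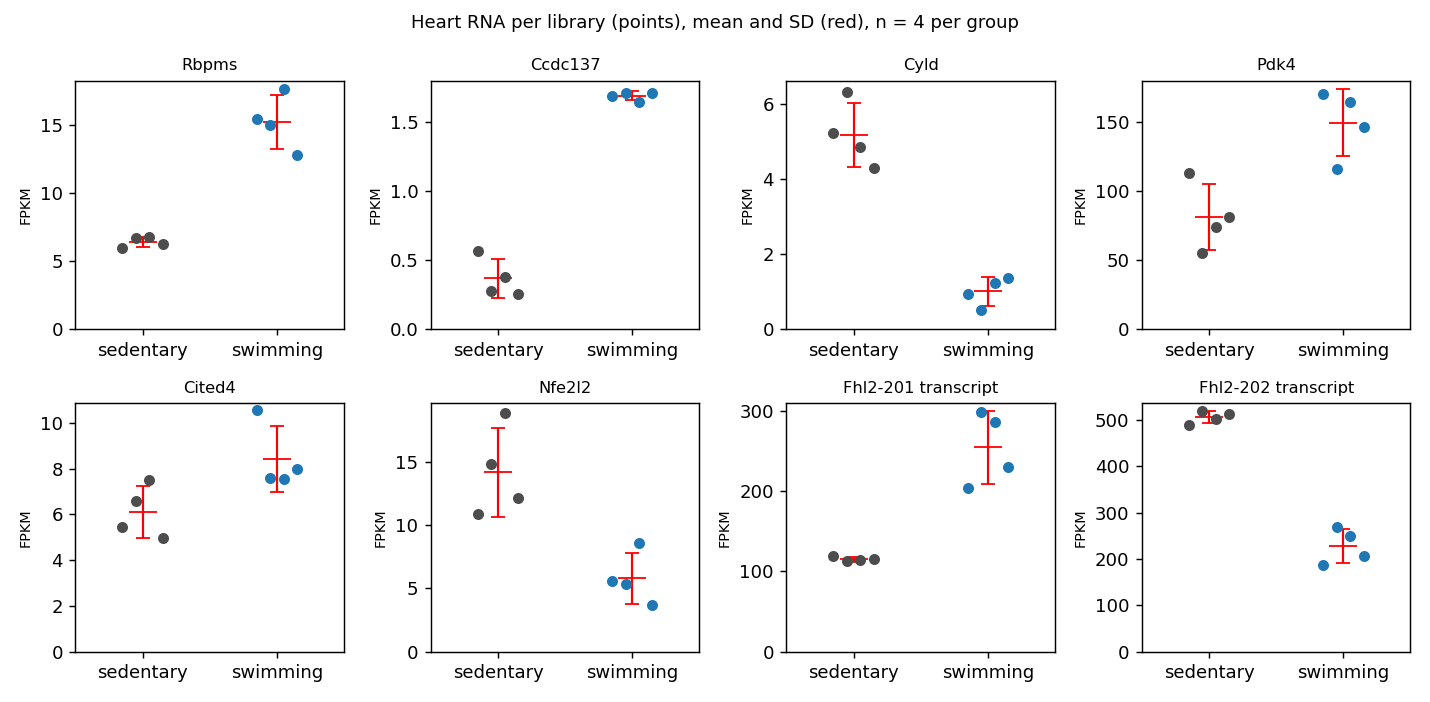
Points give FPKM (vertical axis) in each library of the sedentary and the swimming group, and red bars the mean and SD of 4 libraries. Rbpms and Ccdc137 passed the test over all genes, the 2 Fhl2 transcripts passed the test over transcripts, and Cyld, Pdk4, Cited4 and Nfe2l2 did not pass.

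Nuclear-encoded genes of the respiratory chain were lower as a group in swimming hearts. Of 74 tested members 56 had a negative and 18 a positive log2 fold change, with a median of -0.09, and the list passed camera with the preset correlation (adjusted p = 3.59e-07). With an estimated correlation its adjusted p = 0.710. An unadjusted p below 0.05 was found for 10 members, all with lower means, and 0 passed over all genes or adjusted over the list alone. The complex I subunit gene Ndufc2 had 101.0 ± 2.67 FPKM in sedentary and 88.8 ± 3.27 FPKM in swimming hearts. Cycs, which encodes cytochrome c, had 87.0 ± 3.46 against 75.8 ± 2.93 FPKM, the complex I gene Ndufb3 had 56.9 ± 2.26 against 50.3 ± 1.64 FPKM, and the cytochrome oxidase gene Cox5a had 508.9 ± 19.5 against 451.3 ± 21.9 FPKM. In these 4 genes every swimming library lay below every sedentary one. The mean log2 value of the list per library was 6.59 ± 0.154 in sedentary and 6.49 ± 0.0807 in swimming hearts (exact permutation p = 0.286, and adjusted p = 0.457 over the 8 list means compared), and sedentary replicate 1, at 6.42, lay below 3 of the swimming libraries.

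Heat shock and chaperone genes and immediate-early genes also passed camera on the lower side, and in both lists the means of sedentary replicates 1 and 2 lay within the range of the swimming libraries. The chaperone list had 18 of 25 members with a negative log2 fold change and a median of -0.12 (camera adjusted p = 0.00164, and adjusted p = 0.710 with an estimated correlation). Its members with the smallest p were the co-chaperone gene Dnaja1 (8.29 ± 2.53 against 5.11 ± 1.94 FPKM), the mitochondrial chaperonin gene Hspd1 (88.3 ± 5.24 against 81.6 ± 2.02 FPKM), Hspb7 (293.6 ± 39.2 against 333.9 ± 25.8 FPKM) and Hspb6, a small heat shock protein gene listed at 141.0 and 134.1 FPKM in sedentary replicates 3 and 4 and at 0 in the other 6 libraries. The mean log2 value of the list was 4.33, 4.25, 4.96 and 5.05 in sedentary replicates 1 to 4 and between 4.18 and 4.49 in swimming libraries (exact permutation p = 0.229, and adjusted p = 0.457 over the 8 list means compared). These means take in Hspb6, whose log2 fold change was -4.05 against the list median of -0.12, and it raises those of sedentary replicates 3 and 4. Without sedentary replicate 4, the library with the liver transcripts, the adjusted p of the chaperone list was 0.0801. The immediate-early list had 22 of 28 members with a negative log2 fold change and a median of -0.19 (camera adjusted p = 0.00255, and adjusted p = 0.710 with an estimated correlation). The nuclear receptor gene Nr4a3 had 3.78 ± 2.03 against 1.16 ± 0.637 FPKM, Rgs2 had 10.3 ± 1.96 against 7.23 ± 1.14 FPKM, Egr3 had 3.06 ± 3.17 against 0.415 ± 0.378 FPKM and Jund had 14.3 ± 2.22 against 16.9 ± 1.89 FPKM. Fos was at 10.1 FPKM in sedentary replicate 3 and at 0.617 to 1.22 FPKM in the other sedentary libraries. The mean log2 value of the immediate-early list was 2.28, 2.19, 3.59 and 2.88 in sedentary replicates 1 to 4 and between 2.19 and 2.51 in swimming libraries (exact permutation p = 0.314, adjusted p = 0.457). Without sedentary replicate 3 this list had an adjusted p of 0.737, and without swimming replicate 4 one of 0.0543.

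Macrophage and monocyte markers were higher as a group in swimming hearts. Of 19 tested markers 15 had a positive log2 fold change, with a median of 0.18 (camera adjusted p = 0.0146, and adjusted p = 0.495 with an estimated correlation). The lysozyme gene Lyz2 had 92.2 ± 4.86 FPKM in sedentary and 112.7 ± 6.27 FPKM in swimming hearts and was the 1 marker past the threshold when adjusted over the list alone. The complement gene C1qb had 21.7 ± 1.23 against 26.8 ± 3.56 FPKM, the mannose receptor gene Mrc1 had 10.4 ± 0.441 against 12.6 ± 1.53 FPKM and F13a1 had 14.3 ± 1.39 against 17.8 ± 2.68 FPKM. The mean log2 value of the list was 2.37 ± 0.0950 in sedentary and 2.54 ± 0.0517 in swimming hearts, with every swimming library above every sedentary one (exact permutation p = 0.0286, the smallest this design allows, and adjusted p = 0.229 over the 8 list means compared). The camera call was lost without sedentary replicate 3 (adjusted p = 0.0673), sedentary replicate 4 (0.141) or swimming replicate 3 (0.0737), and without both swimming libraries with the lowest mt-Co1, replicates 2 and 3, the adjusted p was 0.568. In C1qb, Mrc1 and F13a1 these 2 libraries had the highest values. Lymphatic endothelial markers had 6 of 6 positive log2 fold changes, with a median of 0.29, and did not pass (camera adjusted p = 0.0856, and adjusted p = 0.593 with an estimated correlation). Fibroblast markers did not pass (median log2 fold change 0.11, camera adjusted p = 0.0856, and adjusted p = 0.495 with an estimated correlation). Among them Dcn had 171.8 ± 8.48 against 187.7 ± 6.39 FPKM, Lum 19.6 ± 4.18 against 23.2 ± 1.28 FPKM and Pcolce 9.24 ± 3.98 against 12.2 ± 1.70 FPKM, and Fbln1 was past the threshold when adjusted over the list alone. Ventricular cardiomyocyte markers did not pass either. Of 15 tested, 10 had a negative log2 fold change, with a median of -0.05 (camera adjusted p = 0.0856, and adjusted p = 0.495 with an estimated correlation), and their mean log2 value was 8.15 ± 0.0744 in sedentary and 8.12 ± 0.175 in swimming hearts (exact permutation p = 0.771).

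**Figure D3:**
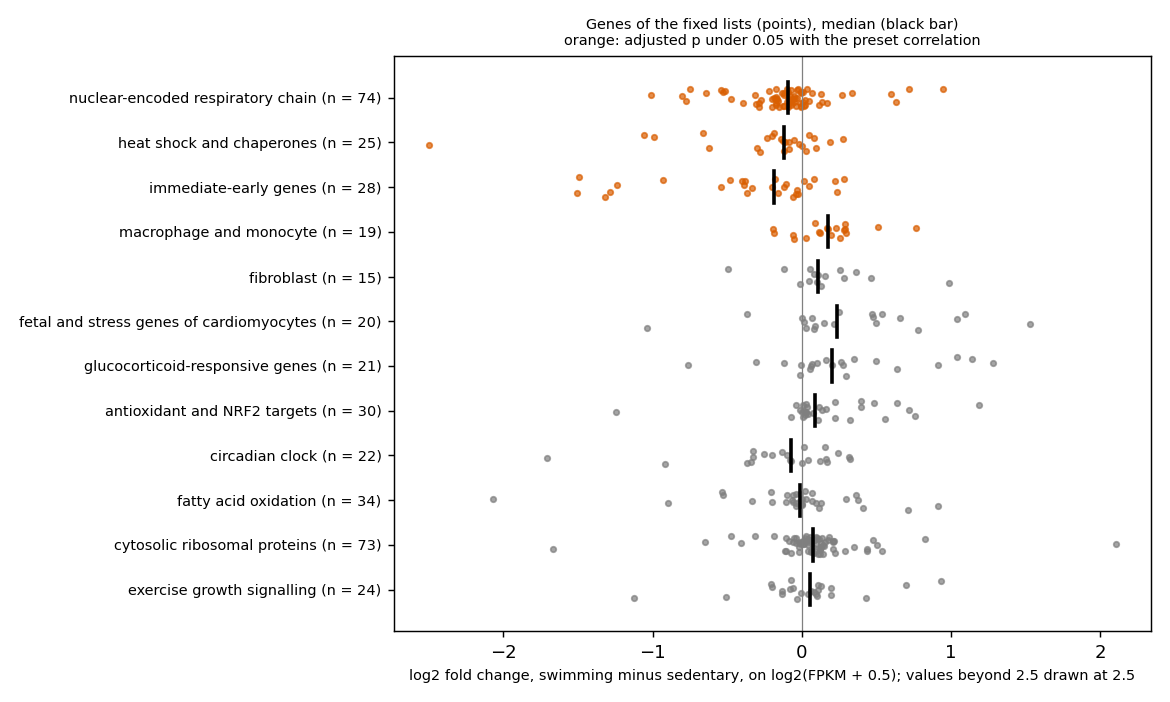
Points give the log2 fold change (horizontal axis, swimming minus sedentary) of each tested gene of 12 fixed lists, and black bars the list medians. Lists in orange passed camera with the preset correlation, values beyond 2.5 are drawn at 2.5, and the medians run from -0.19 for immediate-early genes to 0.23 for fetal and stress genes, a list that did not pass.

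**Figure D4:**
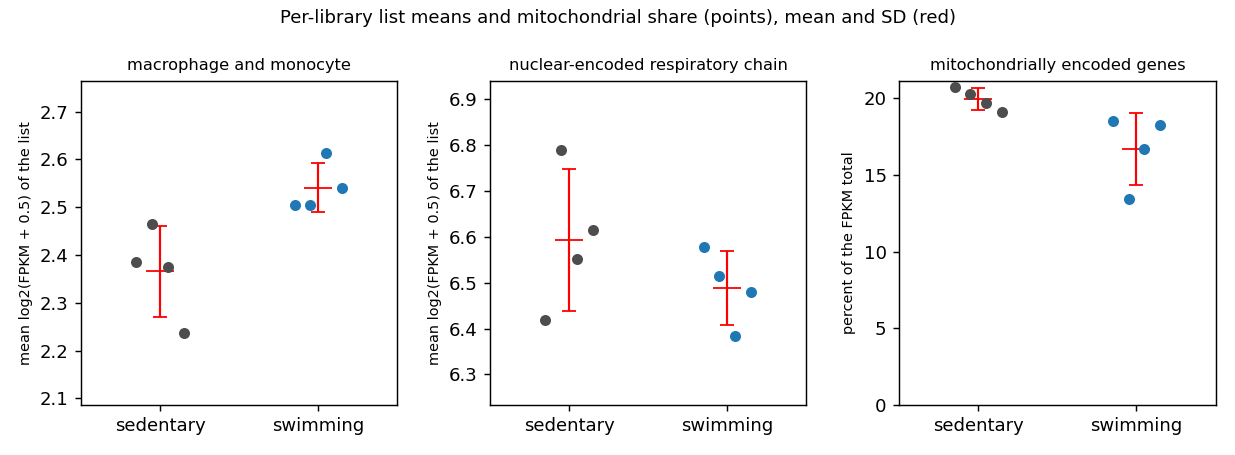
Points give per-library list means of log2(FPKM + 0.5) for macrophage and respiratory chain genes (axes not starting at 0) and the percent of the FPKM total in mitochondrially encoded genes, with red bars for mean and SD of 4 libraries. Macrophage means and mitochondrial shares did not overlap between groups, and respiratory chain means did.

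Genes tied to training and to heart stress were measured with wide spreads, and none passed over all genes. Pdk4, the kinase gene that restrains glucose oxidation, had 81.2 ± 24.0 FPKM in sedentary and 149.7 ± 24.3 FPKM in swimming hearts, with no overlap (log2 fold change 0.91, limma adjusted p = 0.546). Cited4, a transcriptional co-regulator gene linked to exercise-induced heart growth, had 6.12 ± 1.14 against 8.42 ± 1.45 FPKM (limma adjusted p = 0.648). Cebpb, which is set against Cited4 in that response, had 15.4 ± 4.01 against 17.2 ± 5.85 FPKM, and Ppargc1a, a regulator of mitochondrial biogenesis, had 6.18 ± 4.51 against 4.58 ± 0.793 FPKM. In the same growth list Pik3r1 had 21.9 ± 1.84 against 25.1 ± 1.54 FPKM, Akt1 48.1 ± 5.48 against 41.5 ± 3.67 FPKM and Foxo3 9.08 ± 1.25 against 10.4 ± 0.910 FPKM, and the list was far from a call (camera adjusted p = 0.990). The natriuretic peptide genes Nppa (58.8 ± 33.9 against 94.2 ± 33.1 FPKM) and Nppb (204.2 ± 52.9 against 136.6 ± 83.3 FPKM) and the myosin genes Myh6 (554.5 ± 196.2 against 460.8 ± 214.8 FPKM) and Myh7 (7.15 ± 8.82 against 14.3 ± 9.72 FPKM) overlapped between groups. Reads of Myh6 and Myh7 can be shared between these neighbouring paralogs.

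The list of fetal and stress genes reached a camera adjusted p of 0.0620, as did the glucocorticoid-responsive genes, and both had an adjusted p of 0.710 with an estimated correlation. In the fetal list the desmin gene Des had 213.3 ± 38.7 against 292.0 ± 20.3 FPKM, the cardiac actin gene Actc1 had 2180 ± 856.9 against 3259 ± 289.0 FPKM, and the metallothionein genes Mt1 and Mt2 had 27.1 ± 7.12 against 38.6 ± 11.7 and 12.6 ± 2.80 against 28.6 ± 15.5 FPKM. Actc1 was at 3331, 1260, 2019 and 2108 FPKM in sedentary replicates 1 to 4. The assembled transcripts TCONS_00012305 (166.9, 1304, 933.4 and 857.0 FPKM) and TCONS_00012306 (398.9, 1282, 1069 and 928.6 FPKM) ran the other way there. Both were lower in every swimming library. They were set beside Actc1 after the values were seen, and a share of its reads going to them was not tested. The higher Actc1 value is therefore not read as more actin RNA. In the glucocorticoid list Lcn2, the lipocalin gene (0.467 ± 0.276 against 1.59 ± 0.342 FPKM), and Pdk4 were the 2 genes past the threshold when adjusted over the list alone, and Sult1a1 had 6.01 ± 0.714 against 7.48 ± 0.795 FPKM. Fatty acid oxidation genes did not pass (34 tested, camera adjusted p = 0.407). Beside Pdk4, the thioesterase gene Acot2 had 26.3 ± 1.56 against 34.6 ± 5.78 FPKM, the fatty acid transporter gene Slc27a1 had 3.68 ± 0.5001 against 5.07 ± 0.894 FPKM and Hadhb, of the trifunctional protein, had 58.5 ± 7.26 against 46.6 ± 7.49 FPKM.

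Among antioxidant genes, Nfe2l2, which encodes the transcription factor NRF2, had 14.2 ± 3.53 FPKM in sedentary and 5.80 ± 2.02 FPKM in swimming hearts, without overlap (log2 fold change -1.24, limma adjusted p = 0.434), and passed when adjusted over the list alone. Members known as NRF2 targets had means on the other side, with Hmox1 at 4.35 ± 0.292 against 5.94 ± 1.21 FPKM, Prdx1 at 56.1 ± 15.2 against 76.7 ± 1.09 FPKM and Gstm1 at 45.6 ± 6.76 against 60.6 ± 11.3 FPKM. The list had 26 of 30 positive log2 fold changes and did not pass (camera adjusted p = 0.104). Cytosolic ribosomal protein genes did not pass either (73 tested, median 0.07, camera adjusted p = 0.104), with Rpl7 at 139.2 ± 1.85 against 158.0 ± 10.6 FPKM, Rpl4 at 107.2 ± 2.43 against 117.0 ± 3.31, Rpl35 at 71.1 ± 3.01 against 78.5 ± 2.41 and Rps20 at 5.64 ± 0.365 against 6.45 ± 0.264. Many of these genes have pseudogene copies that can take reads. In the circadian list (camera adjusted p = 0.104) Nfil3 had 2.89 ± 0.163 against 3.503 ± 0.258 FPKM, Ciart 5.11 ± 0.415 against 4.22 ± 0.608, Bhlhe40 24.3 ± 1.13 against 19.1 ± 4.63 and Dbp 16.6 ± 2.98 against 13.01 ± 1.64. The senescence gene Cdkn1a (10.6 ± 1.79 against 12.6 ± 3.78 FPKM) and the collagen genes Col1a1 (13.1 ± 4.60 against 14.1 ± 1.96) and Col3a1 (29.2 ± 9.29 against 30.5 ± 3.93) differed by less than the spread between replicates. Under some alternative settings the sign of the difference turned for Cdkn1a, Col1a1, Col3a1, Cebpb and Ppargc1a.

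A test of single transcripts, chosen after the data were seen, called 12 of 22614 transcripts, of which 8 belonged to named genes. The most abundant of these 8 belonged to Fhl2, a LIM-domain gene of cardiac muscle (chromosome 1, 43123074 to 43196984, minus strand). Fhl2-202 fell from 505.9 ± 12.9 to 227.9 ± 37.2 FPKM (limma adjusted p = 0.0389) and the Fhl2 transcript ENSMUST00000008280 rose from 115.1 ± 3.03 to 254.3 ± 45.3 FPKM (limma adjusted p = 0.0492). In the annotation these transcripts share the coding sequence and differ in their noncoding first exon, at 43196651 to 43196984 in Fhl2-202 and at 43163702 to 43163961 in the other, and in the length of the 3' UTR. The sum of all Fhl2 transcripts was 620.9 ± 10.5 against 482.4 ± 82.4 FPKM and did not pass (limma adjusted p = 0.608). Rbpms-202 rose from 0.0745 ± 0.0247 to 7.72 ± 2.15 FPKM (limma adjusted p = 0.00281). It supplied 7.64 of the 8.80 FPKM by which the Rbpms gene sum rose, and the other Rbpms transcripts supplied 1.16. The gene call and this transcript call are thus largely the same result and rest mostly on 1 transcript estimate. Zfp758-202 fell from 2.999 ± 0.216 to 0.174 ± 0.101 FPKM, the Qdpr transcript ENSMUST00000015950 fell from 20.1 ± 1.96 to 7.01 ± 1.46 FPKM and Cyld-204 fell from 4.43 ± 1.05 to 0.573 ± 0.301 FPKM, while Mrps10-204 rose from 0.0287 ± 0.0575 to 1.31 ± 0.321 FPKM.

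Mitochondrially encoded transcripts held 19.97% ± 0.724 of the FPKM total in sedentary and 16.7% ± 2.35 in swimming hearts (exact permutation p = 0.0286, the smallest this design allows). Most of the difference was carried by the values listed for mt-Co1, a cytochrome oxidase subunit gene, at 31432 ± 577.2 FPKM in sedentary hearts and at 28904, 12597, 20079 and 28522 FPKM in swimming replicates 1 to 4. Without mt-Co1 the shares were 7.38% ± 0.868 and 7.39% ± 0.811. Other mitochondrial genes had all-or-none values in the libraries with the lowest mt-Co1. In swimming replicate 2 mt-Co3 was listed at 870.7 FPKM, against 1.26 to 4.28 in the other 7 libraries, and mt-Nd3 at 27.2 FPKM, against 1318 to 2135. In swimming replicate 3 mt-Nd4l was listed at 1443 FPKM, against at most 0.164 elsewhere. These 3 genes were chosen after their values were seen. With any 1 sedentary library left out the exact permutation p of the whole share was 0.0857. The differences then ran from -3.55 to -2.99 points and the groups still did not overlap. The mt-Co1 difference itself did not pass over all genes (limma adjusted p = 0.680), and without both swimming libraries with the lowest mt-Co1, an alternative chosen after the data were seen, limma called 0 genes (1062 at an unadjusted p below 0.05).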

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

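The counts of splits, the distance of transcript shares and the fits with median-of-ratios scaling and quantile normalization were planned before their values were seen, while the bound set on those fits and every other test of an explanation in this part were chosen after the result had been seen. The test of reads moved between transcripts was also changed after its own values were seen. Its first 3 forms set the log2 change of the summed gene against that of the transcript, with a bound of 0.25. They gave a median of 0.361 over all 8 called transcripts of named genes (middle 50% of values 0.254 to 0.876), 0.634 over 6 without Fhl2 (0.330 to 0.884) and 0.327 over the 7 of genes with more than 1 transcript (0.200 to 0.634). They were dropped because the single transcript of Ccdc137 fixes its ratio at 1 and because the log2 change of a transcript starting near 0 is large whatever its gene does. The form reported uses FPKM times length, which is in proportion to reads.

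In 7 of the 158 groups of 4 values looked at, 1 library stood far from the other 3, where chance alone gives 7.9. Fos was at 10.1 FPKM in sedentary replicate 3. Myh7 was at 20.3 FPKM in sedentary replicate 1 against at most 4.16 in the other sedentary libraries. Hadhb was at 69.3 FPKM in sedentary replicate 1, Wwc2 at 6.65 FPKM in sedentary replicate 2 and Zfp329 at 0.408 FPKM in sedentary replicate 3. Cited4 was at 10.6 FPKM in swimming replicate 1 and Rpl35 at 82.1 FPKM in swimming replicate 4.

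Assembled transcripts, which enter no gene sum, also held signal above the sedentary level. TCONS_00013032 averaged 6.25 FPKM in swimming hearts against 0.0573 in sedentary ones, and TCONS_00002771 averaged 1.75 FPKM against 0 in each sedentary library. TCONS_00012305 was listed at 166.9 to 1304 FPKM in sedentary libraries and at 0 in all swimming ones, and TCONS_00012306 at 919.6 ± 376.3 against 59.5 ± 3.54 FPKM. The table pairs none of these with a gene.

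The 12 called transcripts may be a chance yield of this grouping: 9 of the 35 splits of the 8 libraries into 4 and 4 called as many, and the highest other split called 15. For the 2 genes called, 10 of 35 splits gave as many and the highest other gave 5, and for the 860 genes at an unadjusted p below 0.05, 2 of 35 splits gave as many and the highest other gave 951, so that chance is not excluded for any of these counts. An estimation of transcript shares jointly within each group is argued against by the distances of transcript shares over 3596 genes, since the real split ranked 30 of 35 by how far groups lay apart. A move of reads from the other listed transcripts of the gene is argued against for Rbpms-202 and Cyld-204, since those moved the same way and offset -39.2% (95% interval -94.5 to -3.80) and -12.9% (-40.6 to 3.04) of the change, though assembled transcripts, paired with no gene, were left out. Such a move stays open for Zfp758-202 (69.5% offset, 34.7 to 105.7), the Qdpr transcript (43.5%, -0.0274 to 89.4) and Mrps10-204 (-1.84%, -211.3 to 210.9, an interval too wide to decide). For Fhl2 the offset was 55.1% (28.5 to 92.4) for the fall of Fhl2-202 and 181.5% (108.3 to 350.9) for the rise of the other transcript. By the bounds set, the fall is undecided and the rise goes with such a move. These 2 values are the same comparison seen from both sides, since the 2 transcripts carried nearly all of the change. The fall was larger than the rise beyond the interval, so an exchange between them does not account for all of the fall. Swimming itself as a cause stays untested.

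The lower respiratory chain list is likewise not beyond chance: 4 of 35 splits gave it a camera p as small as 1.33e-08, and the smallest of the other splits was 2.35e-13. Median-of-ratios scaling (camera adjusted p = 1.39e-07) cannot decide whether the scaling of the libraries was the cause. Camera compares list genes with the other genes, and 1 factor per library shifts both nearly alike. Quantile normalization can shift them apart, and it weakened the camera adjusted p from 3.59e-07 to 0.000592 but kept the call. Scaling is thus argued against only as far as quantile normalization corrects it. A smaller share of cardiomyocytes in the swimming hearts stays open, because the comparison made cannot decide it. The difference between the respiratory chain and sarcomere means did not differ detectably between groups (exact permutation p = 0.971). The sarcomere mean takes in unstable members such as Myom1, which ran from 4.08 to 234.4 FPKM among sedentary libraries. The median log2 fold change was -0.01 for the sarcomere list and -0.09 for the respiratory chain. Neither the sarcomere list (camera adjusted p = 0.679) nor the ventricular cardiomyocyte markers (0.0856) were called. An effect of swimming also stays open, as untested. For all lists together, 27 of 35 splits called at least 4, and the highest other split called 16, several times the real count, which points to a structure of the samples or to genes of a list varying together more than the preset correlation of 0.01 allows (estimated at 0.0948 to 0.567 in the lists called), and these were not tested apart; that split set sedentary replicate 1 and swimming replicates 1, 2 and 3 against the rest.

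For the fat transcripts in sedentary replicate 4, white adipocyte genes, a list fixed before the data were examined, were highest there in 9 of 11 detected (5 of the 11 reached 0.5 FPKM in another library), and Cfd was at 12.0 FPKM. Unstable all-or-none estimates as the cause are argued against by that share (exact one-sided binomial p = 2.58e-06 against 1 in 8, after multiplying by the 8 libraries, since this one was chosen after its values were seen), and the values are consistent with RNA of fat in this library. For liver, a list of 30 genes was written after Alb and several others had been seen, so that its count cannot serve as a test in favour of liver RNA: all 28 detected at 0.5 FPKM or more in some library had their highest value there, 24 were over 3 times every other library, and 4 reached 0.5 FPKM in another library too. RNA of liver therefore stays open, with Alb at 23.2 FPKM. Tissue carried over at dissection and an exchange of material between libraries were not tested apart, and no biological explanation was tested because the labels give this library no feature of its own.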

How the results depend on the processing

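Depth limits low genes, since absolute depth is unknown and swimming replicate 2 was deeper than the rest. The settings with genes of 1 transcript, without wide-range genes, without both swimming libraries lowest in mt-Co1, per transcript and without mt-Co1 were chosen after the data were seen. Wide-range genes are those whose lowest library was under 5% of the highest. Count tests (edgeR, DESeq2), planned in case reads could be recovered, were not run because they could not. Against 2 genes called by limma, 1 was called with pseudocount 0.1, with a mean of at least 5 FPKM, under quantile normalization and over genes of 1 transcript; 0 were called without both swimming libraries lowest in mt-Co1 (1062 at an unadjusted p below 0.05), and 0 by the exact permutation test per gene, which cannot pass adjustment here (563 at an unadjusted p below 0.05). Per transcript 12 were called. Leaving out single libraries gave 0 to 5 genes, with 4 without sedentary replicate 2 or 3, 1 without sedentary replicate 4 or swimming replicate 1, 0 without swimming replicate 2 (800 at an unadjusted p below 0.05) and 5 without swimming replicate 4, other genes among them. Cyld was called with pseudocount 1 (0.0332) and without wide-range genes (0.0419). Same-numbered libraries did not deviate together over all genes (correlations -0.0540, 0.0145, -0.00327 and 0.0234). These values gave no sign that the numbers pair the samples, but they cannot exclude a shared litter, cage or day. With the replicate block 0 genes were called (651 at an unadjusted p below 0.05) and 7 lists. Log2 fold changes of Rbpms and Ccdc137 were still 1.17 and 1.35, with limma adjusted p of 0.480 and 0.826.

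The 4 lists called, 1 higher and 3 lower, became 0 with estimated correlations. Quantile normalization gave 9 (6 higher, 3 lower) and median-of-ratios scaling 6 (3 higher, 3 lower). A mean of at least 5 FPKM gave 6 (4 higher, 2 lower) and array weights 12 (5 higher, 7 lower). Genes of 1 transcript gave 1, lower. Without both swimming libraries lowest in mt-Co1 there were 10 (2 higher, 8 lower). Leaving out single libraries gave 3 to 11 (11 without sedentary replicate 1, 8 without swimming replicate 1 or 4). The respiratory chain list kept its call in 23 of 24 settings and lost it with an estimated correlation (adjusted p = 0.710), with 1.03e-12 to 0.000138 when single libraries were left out. The chaperone list lost it with an estimated correlation (0.710) and over genes of 1 transcript (0.312), with 9.64e-06 to 0.0801 when libraries were left out. The immediate-early list lost it with an estimated correlation (0.710), at a mean of at least 5 FPKM (0.347), over genes of 1 transcript (0.350) and without wide-range genes (0.0551), with 1.45e-06 to 0.737 when libraries were left out. The wide-range genes include its members Fos, Egr1, Egr2, Egr3 and Nr4a1, each highest in sedentary replicate 3, so that loss does not show that estimates were unstable. The macrophage list lost its call with an estimated correlation (0.495), over genes of 1 transcript (0.175) and without both swimming libraries lowest in mt-Co1 (0.568), with 0.000733 to 0.141 when libraries were left out. The mitochondrial share difference of -3.26 points ranged from -3.86 to -2.15 when libraries were left out and was 0.00267 without mt-Co1, which shows that this transcript carried it; without any 1 sedentary library the exact permutation p was 0.0857. The cause of the other changes was not tested, beyond fewer genes or libraries where the setting removes them. Of 1636 values of the 74 named genes under other settings, 1608 kept sign and side of the threshold and 8, in 5 genes, turned sign. That share says little about the calls, since only Rbpms and Ccdc137 were called to begin with. Rbpms kept its call in 16 of 22 settings and Ccdc137 in 11 of 22.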

Other observations

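Among pathway lists not described in the report, single genes were past the threshold when adjusted over the list alone, while none passed over all genes. In ketone and branched-chain amino acid breakdown this was the lactate and ketone transporter gene Slc16a1, in antigen presentation and complement C4b, in cytokines and NF-kB targets Lcn2, and in the unfolded protein list Herpud1. Abcc9, a potassium channel subunit gene, did so among the pericyte and smooth muscle markers. None of these lists passed camera (adjusted p = 0.115, 0.593, 0.593, 0.810 and 0.820), and in the ketone, unfolded protein and pericyte lists the median, the mean and the direction of the camera test did not share a sign. C4b can share reads with its neighbouring copy C4a. Of the 39 lists tested, 35 did not pass, with camera adjusted p from 0.0620 to 0.990, and the smallest adjusted directional p of fry was 0.205. Fry's mixed test, which asks whether genes of a list change in either direction and does not compare them with other genes, gave an adjusted p of 0.000622 for pericyte and smooth muscle, 0.0290 for fibroblast and 0.0395 for macrophage and monocyte markers.

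Some genes had all-or-none values within a group. Of 6066 genes that reached 5 FPKM in some library, 165 (2.72%) had a lowest library under 5% of the highest, and in 147 of them that spread lay within a group. Mybpc3, a myosin-binding protein gene of the sarcomere, was at 46.9 FPKM in sedentary replicate 2 and at 0.791 and 0.870 FPKM in sedentary replicates 3 and 4, and the homeobox gene Nkx2-5 ranged from 0.169 to 11.1 FPKM among the sedentary libraries. These genes were chosen after their values were seen, and values listed near 0 for genes that cardiac muscle uses throughout are not read here as absence of RNA.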
